A study of Gluconobacter oxydans with 6 samples.

How the data were processed

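Total RNA from 3 bioreactor samples of each strain was depleted of ribosomal RNA and made into strand-specific libraries, per the labels' protocols. The labels number the libraries 1 to 3 within each strain; if they are not separate cultures, p-values measure only the spread between these samples. Per the file headers, the authors trimmed paired reads and deposited, for each library and gene, counts of unique and total gene reads, RPKM and the gene's position on the chromosome of the reference they call a consensus. The authors tested the strains with edgeR, per the submitters' processing notes, which give no version. The aligner was not given in the sources used here.

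The table had 70 columns, 2297 gene rows and 254 blank rows, which were left out. In 24 rows the locus tag carried a trailing space, which was removed, or joined 2 tags, which were kept as 1 row (2 rows). A further 12 columns of values per library, the authors' expression values and transformed values, were not used. End minus start was divisible by 3 in 97.6% of rows, so it is taken as coding length; positions are given as deposited, and whether they count from 0 or 1 was not settled. The strand is not used here.

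Unique gene reads, the deposited counts of reads placed at 1 site, were the main measure, and total gene reads were tried as an alternative. The deposited RPKM were used only to recover the number of reads each library was scaled to, of which the gene rows hold 96.4% to 99.2%. Rows that took at least 1% of total gene reads in every library, 8 in all, were left out as ribosomal RNA; the files do not name them, and the rule was set after the values were seen. Genes that share reads with a near-identical copy are undercounted in unique reads.

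Genes were filtered with filterByExpr, scaled with TMM factors and fitted with a strain term in edgeR 4.0.16 (R 4.3.3). The test was the robust quasi-likelihood F test with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. The standard error was the log2 fold change divided by the square root of F. CPM are unique reads scaled to the TMM-adjusted library size, and log2 CPM had a prior count of 2. With 3 against 3 libraries an exact two-sided permutation test of a single value cannot go below 0.10, so none is given. Floors rest on 3 counts and, as reads carry no molecular identifiers, cover counting error only.

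The samples, main test and rule for named genes were fixed before the data were examined, as were these alternatives: RLE size factors, library totals alone, no filter on low counts, DESeq2 1.42.0, limma-voom (limma 3.58.1), edgeR's exact test, a replicate block, the ribosomal rows kept, a stricter threshold of 0.01 and each library left out in turn. Chosen after seeing the data were 1 surrogate variable (sva 3.50.0), a covariate that sets parental 1, delta-goxR 1 and delta-goxR 2 apart from the other 3 libraries, total gene reads, and leaving out both libraries numbered 1.

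The rule for named genes took the deleted gene, hsdR, its direct neighbours on the chromosome, up to 12 called genes per direction with groups that do not overlap and a mean count of 30 or more, and members of 20 gene lists. The files do not pair locus tags with gene names. GOX0974 was taken as goxR from what is known of the study, hsdR was not analysed here, and the 20 gene lists were not tested. Since the test called no gene, 2 tags per direction were chosen after their values were seen, by the lowest p in the authors' deposited table, and the 5-gene run was chosen likewise.

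The fits were tested on simulated data: counts drawn for the 2074 tested genes from their means, dispersions and the library sizes, with 200 genes changed 4-, 8- or 16-fold. There were 4 calls among the unchanged genes. A second simulation added a clean difference between libraries and used a single dispersion. That dispersion was lower than the common dispersion of the data (0.337, or 0.146 with the surrogate variable). There the fit with 1 surrogate variable recovered 190 of the 200 genes, with 7 calls among the unchanged. The fit without it recovered 102, with 0. The surrogate variable matched the added difference at a correlation of 0.9998, so these rates do not carry over to the data. Libraries of a strain were compared for duplicates: chi-square per degree of freedom was 21.1 or more for each pair, far above sampling noise.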

Results

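RNA of Gluconobacter oxydans, an acetic acid bacterium that oxidises sugars and sugar alcohols incompletely in its periplasm, was sequenced from 2 strains. The parental strain lacked hsdR, a restriction endonuclease gene, and the delta-goxR strain lacked goxR as well. The goxR gene encodes an FNR-type transcriptional regulator. Both were grown in bioreactors on 220 mM mannitol at pH 6 with 15% dissolved oxygen to an OD600 of 2.5. The gas was then changed to 2% oxygen and 98% nitrogen, and cells were harvested 20 min later. There were 3 libraries per strain. The comparison asked which transcripts differed without the regulator once oxygen had become limiting.

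Parental libraries 1, 2 and 3 held 10294813, 5120414 and 4319950 total gene reads, and delta-goxR libraries 1, 2 and 3 held 13209469, 4612067 and 5678067. Of these, 8 rows with the length, copy number and abundance of ribosomal RNA genes took 96.0%, 95.6% and 85.5% in the parental libraries and 94.5%, 81.6% and 88.1% in the delta-goxR libraries. Uniquely placed reads outside these 8 rows numbered 403213, 219548 and 614947 in the parental and 716640, 834464 and 660993 in the delta-goxR libraries. The median gene had 24 unique reads in the shallowest library, parental 2, and 165 in delta-goxR 1.

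The transcript of the deleted gene was read first. GOX0974, the locus tag of goxR, lies at chromosome positions 1072819 to 1073416 and has a coding length of 597 bp. It had 29, 8 and 19 unique reads in the parental libraries, which was 44.8 ± 14.3 CPM (SD, n = 3), and 0 reads in each delta-goxR library. A count of 0 allows up to 2.62, 5.29 and 4.96 CPM in delta-goxR libraries 1, 2 and 3 (3 counts per library). Over the whole group, with a floor of 3 counts for all 3 delta-goxR libraries together, GOX0974 was at least 34.5-fold lower than in the parental group. This bound takes the parental rate, which rests on 56 reads, as exact. It was the 1 row with unique reads in every parental library and none in any delta-goxR library. The adjusted p of GOX0974 was 0.181 in edgeR's quasi-likelihood test, 0.000232 in DESeq2 and 7.53e-05 in edgeR's exact test. Its false discovery rate in the authors' deposited table was 0.245. The genes next to GOX0974 did not pass edgeR's test. GOX0973, at 1071729 to 1072548, had 79.9 ± 43.2 CPM in the parental and 80.0 ± 56.2 CPM in the delta-goxR libraries (SD, n = 3). GOX0975, at 1073490 to 1073925, had 450 ± 130 CPM in the parental and 218 ± 143 CPM in the delta-goxR libraries (SD, n = 3). Its log2 fold change was -1.04 (SE 0.56, adjusted p 0.996 in edgeR). Without single libraries the log2 fold change ran from -1.75 (without delta-goxR 3) to -0.78 (without delta-goxR 1).

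**Figure D1:**
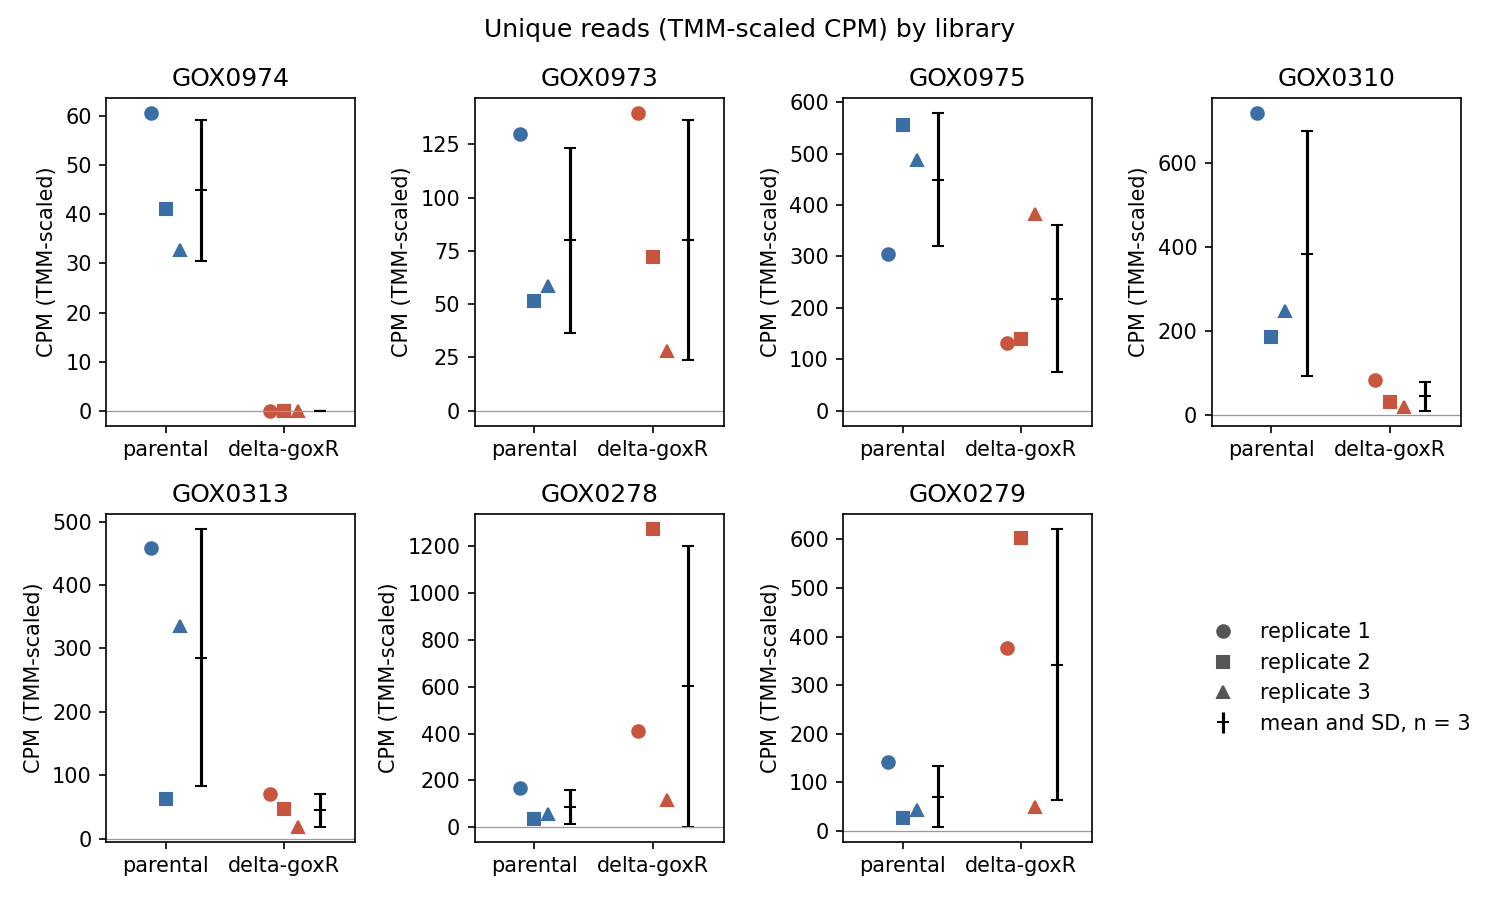
Unique reads as TMM-scaled CPM (linear axes that include 0) of the goxR tag, its neighbours and the 4 other named genes in each of the 6 libraries. Symbols mark the replicate, colours the strain, and black bars the mean and SD of 3 libraries; GOX0974 is at 0 in the 3 delta-goxR libraries and between 32.7 and 60.6 CPM in the 3 parental libraries.

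Besides the deleted gene, the lowest p values in the downward direction in the authors' deposited table belonged to GOX0310 and GOX0313, which lie in a run of 5 adjacent genes between 328434 and 333470. GOX0310, at 328434 to 329661, had 384 ± 292 CPM in the parental and 44.5 ± 34.4 CPM in the delta-goxR libraries (SD, n = 3), and its values in the 3 delta-goxR libraries lay below those in the 3 parental libraries. Its log2 fold change was -3.08 (SE 0.72), with an unadjusted edgeR p of 0.0016 and an adjusted p of 0.996. GOX0313, at 331429 to 332461, had 285 ± 203 CPM in the parental and 44.6 ± 25.9 CPM in the delta-goxR libraries (SD, n = 3), with a log2 fold change of -2.67 (SE 0.74, adjusted p 0.996 in edgeR), and its groups overlapped. The mean log2 fold change of the 5 genes was -2.50, and it was -1.67 without parental 1 and -3.52 without delta-goxR 1. For GOX0310 these fits gave -2.26 and -3.94. In the authors' deposited table the false discovery rate was 0.0569 for GOX0310, the lowest of all rows, and 0.232 for GOX0313. The 5-gene run had 1032, 62 and 613 unique reads in the parental libraries and 437, 105 and 40 in the delta-goxR libraries. Scaled to library size, its mean log2 CPM was 8.51, 5.50 and 7.45 in parental 1, 2 and 3. It was 6.12, 4.94 and 3.88 in delta-goxR 1, 2 and 3, so parental 2 lay below delta-goxR 1. In delta-goxR 1 the run lay near the low end of that library. There GOX0313 (1032 bp) had 69.8 CPM and GOX0314 (984 bp) 92.5 CPM, against a 10th percentile over genes of 65.7 CPM per kb. In parental 2 that percentile was 16.7. The overlap may therefore rest on values near the floor of delta-goxR 1. Of the 5 genes, only GOX0310 had groups that did not overlap.

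**Figure D2:**
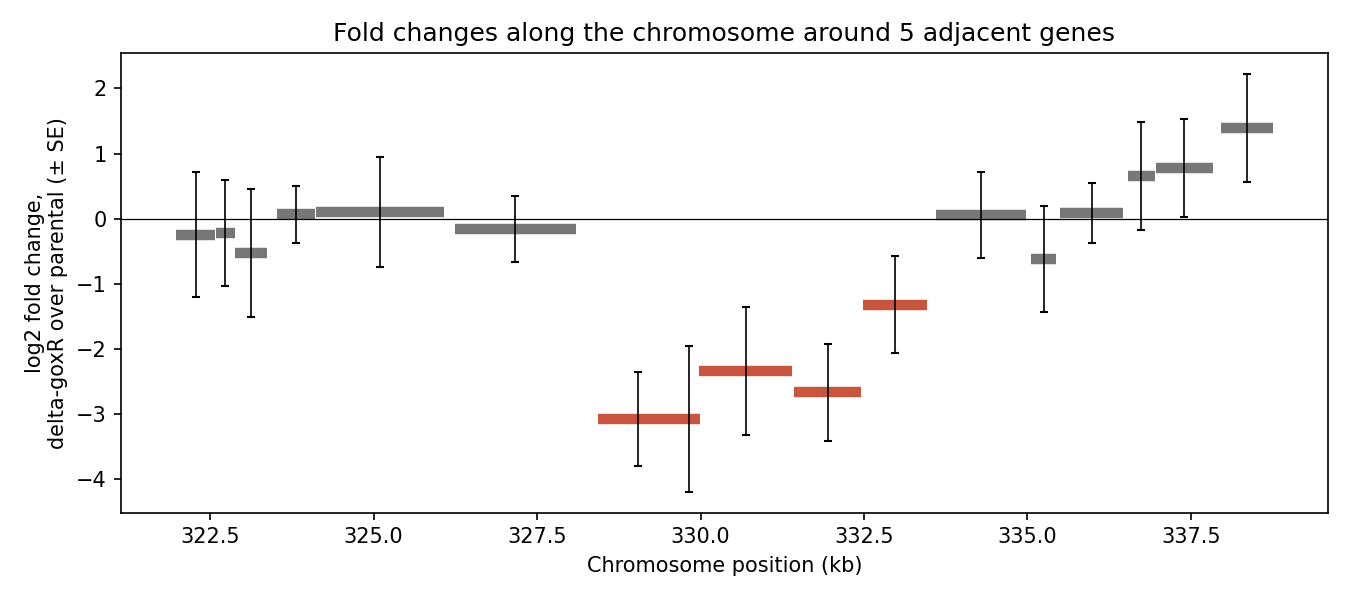
Log2 fold change (delta-goxR over parental, vertical axis) against chromosome position in kb for tested genes around the 5-gene run, with bars for the standard error. Each gene is drawn as a line from its start to its end; the 5 genes of the run, in red, have log2 fold changes from -3.08 to -1.33.

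In the upward direction, GOX0278 and GOX0279 had the lowest p in the authors' deposited table. GOX0278, at 293824 to 295252, had 86.8 ± 72.1 CPM in the parental and 601 ± 601 CPM in the delta-goxR libraries (SD, n = 3), a log2 fold change of 2.76 (SE 0.89, adjusted p 0.996 in edgeR). GOX0279, at 295257 to 296283, had 70.3 ± 62.8 CPM in the parental and 342 ± 279 CPM in the delta-goxR libraries (SD, n = 3), a log2 fold change of 2.24 (SE 0.88, adjusted p 0.996 in edgeR). Single libraries moved both values. GOX0278 had a log2 fold change of 1.58 without delta-goxR 2 and 3.67 without parental 1, and GOX0279 had 1.55 and 3.24. With 1 surrogate variable in the fit the values were 2.33 for GOX0278 and 1.61 for GOX0279, and with the library cluster as a covariate 1.84 and 1.17. The groups overlapped for both genes: parental 1 had 169 CPM of GOX0278 and delta-goxR 3 had 117 CPM. In the authors' deposited table the false discovery rate was 0.727 for GOX0278 and higher for GOX0279.

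Across all 2074 genes tested, edgeR's quasi-likelihood test called 0 genes higher and 0 genes lower in delta-goxR, and so none changed at least 2-fold. At an unadjusted p under 0.05 it gave 29 genes, 6 higher and 23 lower, where 104 would arise by chance. DESeq2 and edgeR's exact test each called 1 gene, GOX0974, and gave 35 and 33 genes at an unadjusted p under 0.05. Limma-voom called 0 genes and gave 22. The false discovery rate in the authors' deposited table was under 0.05 for 0 rows, and 14 had an unadjusted p under 0.05. The count of 29 was 327 without parental 1 (224 higher, 103 lower), 18 without parental 2 and 10 without parental 3. It was 36 without delta-goxR 1 (6 higher, 30 lower), 10 without delta-goxR 2 and 92 without delta-goxR 3. Without both libraries numbered 1 it was 231 (146 higher, 85 lower). The balance of higher and lower genes thus turned round in the fits without parental 1. There the remaining parental libraries stood together in the grouping given below. On its other side lay delta-goxR 2 and, where it was kept, delta-goxR 1. Strain and that grouping were partly confounded in these fits, so their counts cannot be read as a response to the deletion. The main fit was unbalanced too, to a lesser degree. Delta-goxR 1 and delta-goxR 2 lay with parental 1 in that grouping, and delta-goxR 3 with parental 2 and parental 3. The 29 genes of the main fit and the fold changes named above can therefore carry part of that grouping. The median standard error of a log2 fold change was 0.60. In counts simulated for this comparison over 2074 genes, the test recovered 26.9% of 67 genes changed 4-fold, 74.6% of 67 changed 8-fold and 90.9% of 66 changed 16-fold. Even there, most 4-fold changes were not recovered. These rates hold for 200 changed genes, where the adjustment is milder than with few, and for libraries drawn independently, without the grouping given below. In the deposited data GOX0974, at least 34.5-fold lower, had an adjusted p of 0.181 in edgeR's quasi-likelihood test. With 29, 8 and 19 parental reads and an SE of 1.11, it speaks for genes with few reads only. In such genes the 0 calls therefore do not exclude changes of 8- or 16-fold. For other genes the simulated rates, which hold for milder conditions, do not exclude them either. For 63 genes, 3.04% of those tested, the values of the groups did not overlap (35 higher, 28 lower). The average share over all splits is 10% by arithmetic, however the libraries vary. Taking 10% as the share expected for the strains, and 104 as the number of genes, assumes libraries that vary independently. These did not, and other splits of them gave from 7 to 937 genes at an unadjusted p under 0.05. Values below 10% and 104 therefore cannot be read as fewer changes than chance.

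The libraries did not group by strain. The first principal component held 65.6% of the variance and placed parental 1, delta-goxR 1 and delta-goxR 2 on one side and parental 2, parental 3 and delta-goxR 3 on the other. Spearman's correlation across genes was 0.923 between parental 1 and delta-goxR 1, and 0.694 and 0.721 between parental 1 and the other parental libraries. It was 0.946 between parental 2 and parental 3 and 0.935 between parental 2 and delta-goxR 3. Delta-goxR 2 lay between these libraries: its correlation was 0.887 with parental 1, 0.860 with delta-goxR 3, 0.827 with parental 3, 0.798 with delta-goxR 1 and 0.784 with parental 2. It stood alone on the second component, which held 17.7% of the variance. Genes are not independent replicates. The 10th percentile of unique reads per kb, scaled to the library total without TMM factors, was 56.9 in parental 1 and 105 in delta-goxR 1, and between 12.8 and 19.1 in the other 4 libraries. With TMM factors it was 47.9 and 65.7, and between 13.5 and 24.9 in the other 4. The 10 most abundant genes took 23.9% of unique reads in delta-goxR 2 and 18.7% in parental 1, against 12.5% to 13.6% in the other 4.

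**Figure D3:**
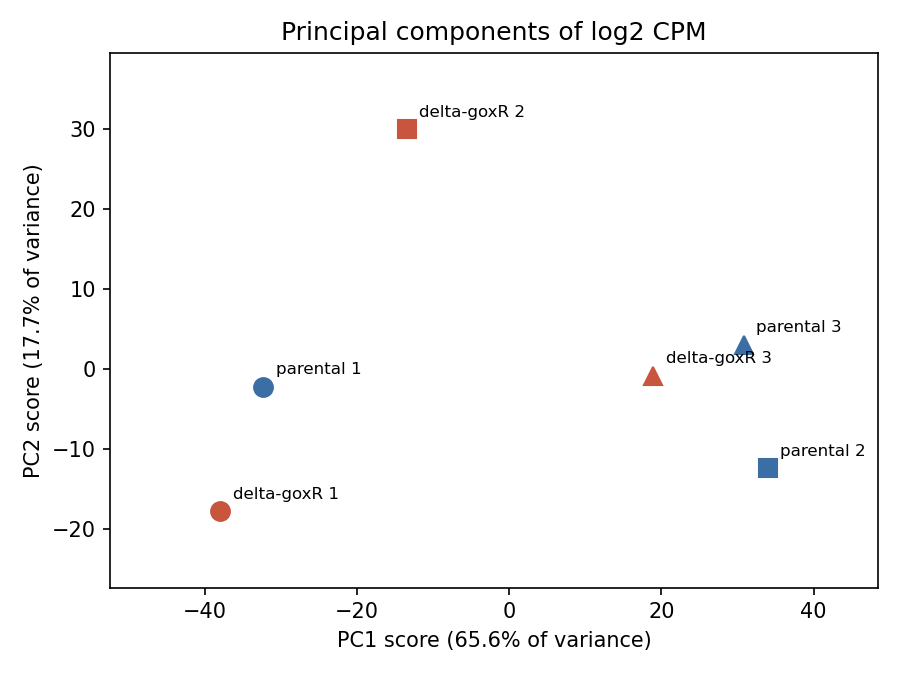
Scores of the 6 libraries on the first 2 principal components of log2 CPM, with the percentage of variance on each axis. Colours mark the strain and symbols the replicate; parental 1 lies beside delta-goxR 1, away from parental 2 and parental 3.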

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

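The surrogate variable, the cluster covariate, total gene reads and the fits without both libraries numbered 1 were chosen after seeing the data. The count of genes higher in delta-goxR was 0 in all 19 alternatives. The count of genes lower was 0 in 15 of 19, and 1 with DESeq2, 1 with edgeR's exact test, 3 with 1 surrogate variable and 3 with the library cluster as a covariate; the counts of genes changed at least 2-fold were 1, 1, 3 and 3 in these and 0 in the other 14 of 18 alternatives. The goxR transcript, GOX0974, had a fitted log2 fold change of -7.75, which depends on the prior count and is no bound; it passed the threshold with DESeq2 (-7.47), the exact test (-7.75), the surrogate variable (-8.02) and the cluster covariate (-8.01). Over its 18 alternatives the adjusted p ran from 7.53e-05 to 1.00, and without single libraries the fold ran from -7.97 to -7.45. Each fit without a library called 0 genes. GOX0310 had negative log2 fold changes in its 18 alternatives, from -3.94 to -2.26. GOX0973 had a log2 fold change of -0.0029 (SE 0.64) in the main fit, so its sign was not determined. It changed sign with RLE factors (0.0106), library totals (0.22) and DESeq2 (0.0021), and without single libraries ran from -0.69 to 0.54. Its standard error was at least 0.61 in these. Why the other values moved between settings was not tested. The gene list tests were not run, with no names paired to the tags.

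Whether the numbers pair the libraries could not be settled. Deviations of same-numbered libraries correlated at 0.69, -0.26 and 0.57. Parental 1 and parental 3 had their best match in the other strain under the same number. Parental 2 correlated best with delta-goxR 3 (0.70). With a replicate block, edgeR called 0 genes higher and 0 lower. It gave 83 at an unadjusted p under 0.05 (51 higher, 32 lower, against 6 and 23 without the block). GOX0974 and GOX0310 stayed above the threshold, each with an adjusted p of 0.0708 in this fit. The median standard error was 0.63 in the 692 genes with the lowest mean CPM, 0.50 in the next 691 and 0.71 in the 691 with the highest, so it was not depth alone that limited the precision.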

Other observations

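The tests on the 5-gene run, the low percentiles, the swapped labels, the counts of calls in other splits, the surrogate variable and the cluster covariate were chosen after the results were seen; those on thinned libraries, abundant genes and gaps between genes were chosen before.

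Neighbouring genes had alike fold changes. Across genes, the log2 fold changes of 927 neighbours less than 50 bp apart correlated at Pearson's r = 0.624 (Spearman's rho 0.590), against r = 0.162 (rho 0.223) for 330 neighbours 200 bp or more apart. The difference of 0.462 had a one-sided permutation p of 1e-04 over 10000 permuted gap classes, the smallest they can give, although neighbouring pairs are not independent. With 1 surrogate variable in the fit, r was 0.596 against 0.144, and rho was lower, 0.350 against 0.128. A candidate explanation is that closely spaced genes share a transcript. Reads that span both neighbours were tested with 355 pairs separated by an intervening gene of 600 bp or more, with both gaps under 50 bp: r was 0.429, still 0.267 above that of distant neighbours (one-sided permutation p 0.001), which argues against such reads as the whole cause. Strand was not used, so transcripts were not traced.

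The 5-gene run between 328434 and 333470, with GOX0310 and GOX0313, had a mean log2 fold change of -2.50. Loss of the run from the mutant's genome is argued against by its reads, of which the delta-goxR libraries held at least 40 each. The split along the first principal component as the whole cause is argued against too, since with 1 surrogate variable in the edgeR fit the mean was -3.23. This covers that split alone and leaves other variation between libraries in place. GOX0310 then had a log2 fold change of -3.72 (SE 0.40, adjusted p 0.0026, with a range of 0.0014 to 1.00 over its alternatives). GOX0974 had an adjusted p of 0.0136 and the gene at 329657 to 329987 one of 0.0403. These adjusted p take the surrogate variable as known, although it was estimated from the same counts with the strain term kept in the model. The gene at 329657 to 329987 had 2 reads in parental 2 and 1 each in delta-goxR 2 and delta-goxR 3. Which further gene of the run passed depended on the covariate: with the library cluster in its place GOX0310 (0.0014), GOX0974 (0.0046) and GOX0313 (0.0434) passed and the gene at 329657 to 329987 had 0.112, while GOX0313 had 0.0856 with the surrogate variable. The 10 splits of 6 libraries are too few to say whether chance can be excluded: the largest 5-gene mean was 2.50 in size for the real split and 3.78 for the highest other, and 4 splits, the real one included, had a mean of 2.50 or more. This same run was also the largest window in 3 splits that mix the strains, with a mean of 3.01 in size for parental 1, parental 3 and delta-goxR 1 against the rest, above that of the strains, so it varied between libraries in ways the strains do not account for. An even background in delta-goxR 1, given below, may raise the run's reads there and so the mean of that split. Whether it did was not tested. Lower transcription of the run without the regulator stays open as an untested hypothesis.

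The libraries differed in a way the strains do not explain. The strains gave 0 calls with edgeR's quasi-likelihood test (29 genes at an unadjusted p under 0.05, 1 call each with DESeq2 and the exact test). The highest of the other splits, parental 1, delta-goxR 1 and delta-goxR 2 against the rest, gave 655, which points to a structure of the samples; it follows the sign of the first principal component, so it restates that grouping and adds no separate support for it. The 10 splits are too few for a share under 0.05, and a count of 0 is reached by any split, so they say nothing of the strains. Depth is argued against, since this split still called 560 genes after every library was thinned to 219548 reads, and so is a swap between the strains, since the delta-goxR libraries held 0 reads of GOX0974 where the parental rate would give 51.2, 25.3 and 27.1.

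An even background over all genes, such as genomic DNA, may be part of it in parental 1 and delta-goxR 1, where the 10th percentile of unique reads per kb was at least 2.97 times that of parental 2, parental 3 and delta-goxR 3 when scaled to library totals and 2.29 times with TMM factors. In delta-goxR 2 it was 0.885 times the highest of those on library totals and 1.19 times with TMM factors, both under the 2 times set for this test, which argues against a background of that size there and leaves a smaller one open. It was not the whole difference in the first pair: among the 208 most abundant genes, where such a background adds little, the SD of the log2 ratio to the other libraries was 1.67 or more, 2.01 times the largest SD among parental 2, parental 3 and delta-goxR 3 (0.830). A difference in the state of the cultures at harvest was not tested.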
